A study of Arabidopsis thaliana and blank sample with 1375 samples.

How the data were processed

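Protoplasts from root meristems of 5-day-old Arabidopsis thaliana seedlings were sorted by fluorescence into plates, 1 cell per well, and sequenced with Nextera XT libraries, per the labels' protocols. The series held 1375 libraries from 7 reporter lines and 5 empty wells, spread over 10 library pools. The lines held 570 libraries of deltaP3Y, 191 of CALS7, 187 of P3Y, 185 of PD3, 95 of CD3, 95 of N57 and 47 of N73. CALS7 and PD3 shared pools 14251 to 14255, CD3 was in pools 14251 to 14253, N57 and N73 were in pool 14259, P3Y was in pools 12100 and 14259, and deltaP3Y was in pools 17311 to 17313. The empty wells, 1 in each of pools 14251 to 14255, are called wells 1 to 5. A pool is the sequencing library number in a library's title, and it was treated as a technical batch. Reads were handled with HISAT2, Picard and Cuffnorm against build TAIR10, per the submitters' processing notes, and versions were not given in the sources used here. The deposited signal of each gene in each cell was an estimated number of fragments divided by one factor per cell, per the labels and the values in the table. Because 1 sorted cell went into each well, no caller of doublets was run.

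The factor of each cell was recovered from its most frequent low value, and the total over that value was taken as the cell's number of fragments. Of the low values, up to 20 fragments, a median of 96.04% lay within 0.1 of a whole number of fragments, and the lowest share in a kept cell was 87.8%. A gene counted as detected from 0.5 fragments. Cells were kept with at least 1000 genes above 0 and at most 20% of the total from chloroplast and mitochondrial genes, of which the table listed 285. This kept 1220 cells (177 of P3Y, 189 of CALS7, 177 of PD3, 95 of CD3, 83 of N57, 39 of N73 and 460 of deltaP3Y) and removed 150 libraries, 113 of them over the organelle limit and 70 with too few genes, and a library could fail both limits. No library was an exact copy of another. Of 32824 gene identifiers, 32539 matched the reference gene table of assembly TAIR10.1, which was used for gene names only. No coordinates are given, because the reference differs from the build of the files.

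Clusters were called from natural log values of nuclear genes scaled to 10000 per cell, on 2000 variable genes, 20 principal components, 15 neighbours and the Leiden method at resolution 1. All 134 genes of 14 fixed lists were left out of the clustering and served only to name clusters and to describe groups. A marker supported a cluster when its mean log value there was at least 0.25 and at least its mean over clusters. A class name needed 3 supporting markers and at least 1 in 2 markers of a list. Ties between classes, leading genes of another class and shallow clusters without a marker among their 10 leading genes were left unnamed. The marker lists were fixed before the data were examined, whereas this naming rule was set after the clusters had been seen, and each unnamed cluster's share is given for the lines that hold it. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only.

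The level of a gene in a line was the mean deposited signal over kept cells of that line in a pool, averaged over the pools that a pair of lines shared. Ratios were log2 with a pseudocount of 1, taken within each pool and averaged over pools. A list median is the median over members of these averaged ratios, so it can lie outside the range of the medians within single pools. For each pair the rule named the 10 genes with the largest mean ratio in each direction among genes with a level of at least 20 in the higher line and at least 2-fold in the same direction in every shared pool. It also named each member of the fixed lists that differed at least 2-fold in the same direction in every shared pool, and members of the early phloem and late sieve element lists where an example was needed. The lists held early phloem regulators (17 genes), late sieve element genes (12), companion cell genes (9), columella and root cap genes (8), stem cell niche and PLETHORA genes (6), and procambium and xylem genes (20). The remaining lists held pericycle (4), endodermis (6), cortex (2), epidermis (5), cell cycle (21), ROP signalling (11), wounding and protoplasting stress (8) and reference genes (5). Each list median was placed among the medians of 10000 random lists of genes of similar level, drawn from 200 neighbouring genes, and the percentile is the share of random lists with a lower median. The median ratio over nuclear genes with a level of at least 20 in either line is given as the shift of a pair. The comparison of deltaP3Y with P3Y had no shared pool and was limited to list members and cluster shares, and a member counted as higher or lower when every pool of one line lay above every pool of the other.

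The 734 cells of sieve-element-like clusters were ordered by diffusion pseudotime on 1000 variable genes of one fixed part of the genome, list genes left out, starting from the cell with the highest mean of early phloem regulators. A second order, also fixed beforehand, ranked them by the first principal component, and both orders were divided into 5 bins. List members detected in at least 10% of ordered cells were described, along with the 10 genes of the remaining part with the highest and the 10 with the lowest rank correlation with the order within lines, averaged over lines with at least 20 ordered cells. A line or pool counted toward a direction along the order with at least 5 cells in both end bins. On simulated data with 600 cells and 32539 genes, for the order along the sieve element trajectory, pseudotime from the true first cell and the first principal component both gave a rank correlation of 0.999 with the true order, but pseudotime from the middle cell gave 0.228. The simulated order was a single smooth course with counting noise. It held no cell cycle phases, lines or pools, by which the real cells differ. On simulated data of 32824 genes, the ratios recovered 72% of 100 genes changed 4-fold and 98% changed 16-fold with the pools of PD3 against CALS7, 91% and 100% with those of CD3 against CALS7, and 98% and 100% with that of N57 against P3Y. These simulations split the cells of a single line at random within pools, CALS7 for the comparisons with CALS7 and P3Y for the other. The groups therefore did not differ in cell types as the real lines do, and wrongly called genes were not counted. The changed genes were drawn only from genes clearly above the minimum level.

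Alternatives planned before the data were examined changed the cell filter (500 or 2000 genes, no organelle limit), the scaling of cells (each to a total of 1000000, or median-ratio factors), the pseudocount (10), the minimum level, the size rule (4-fold), the clustering (resolution 0.5 or 2, list genes kept in, log values centred per pool), the cells used and the pools used. A minimum of 50000 fragments per cell, medians over cells in the single-pool pairs, P3Y cells of its other pool in place of the shared pool, names from 1 in 3 markers, a start at the first cell by the first principal component and thinning to 50000 recovered fragments were chosen after seeing the data. A value counted as moved when it changed by over 1.5-fold, and as reversed when a value of at least 2-fold changed sign, a size limit that was set after a first run. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.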

Results

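Cells of the Arabidopsis root meristem were isolated from 7 reporter lines and sequenced 1 by 1, in a study of how cells mature along a trajectory. Line deltaP3Y held 570 libraries, CD3 and N57 95 each and N73 47, beside 5 empty wells, and the larger numbers of P3Y, CALS7 and PD3 are given with the processing. The labels gave PSE as the possible cell type of 6 lines, and PSE, MSE, procambium or columella for deltaP3Y, without explaining the abbreviations or the reporters. CALS7 is the name of a line here unless the text says CALS7 gene. Kept cells had a median of 607215 fragments and 6622 detected genes. The median number of fragments and its range was 487925 (2855 to 3889439) in P3Y, 1284367 (3064 to 5385057) in CALS7, 2182776 (5141 to 5788376) in PD3 and 1492663 (6299 to 4369241) in CD3. It was 714189 (4242 to 4445973) in N57, 926964 (3774 to 4698196) in N73 and 229203 (7051 to 2855240) in deltaP3Y. Each line counted as 1 sample, with no replicates named in the labels, so no test between lines was possible and all differences are descriptive.

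The first question was which cell types each reporter line captured. Cells of clusters with markers of early phloem or of late sieve elements, called sieve-element-like, made up 100% of N73 cells (39 of 39, 95% interval from 90.97%), 98.9% of CALS7 (96.2 to 99.9%) and 98.9% of CD3 (94.3 to 99.97%). Their share was 81.4% in P3Y (74.8 to 86.8%), 66.7% in PD3 (59.2 to 73.6%) and 60.2% in N57 (48.9 to 70.8%). In deltaP3Y the share was 22.2% (18.5 to 26.3%), while 28.04% (23.98 to 32.4%) of its cells were columella- or root-cap-like, and the remaining 49.8% belonged to unnamed clusters. Root-cap-like cells made up 0.565% of P3Y and 0.565% of PD3, 1 cell in each. None was found in the other lines, which allows up to 1.93% in CALS7, 3.81% in CD3, 4.35% in N57 and 9.03% in N73.

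Sieve-element-like cells fell into different clusters by line. CALS7 cells lay in cluster 5 (33.3%), cluster 4 (31.7%), cluster 10 (18.5%) and cluster 13 (11.6%), and N73 cells in clusters 10 (28.2%), 4 (25.6%) and 13 (25.6%), where all or most late sieve element markers were supported. CD3 cells lay in clusters 9 (26.3%), 7 (21.1%) and 8 (20%), and PD3 cells in clusters 8 (23.7%) and 9 (16.9%), whose leading genes included the cyclins CYCA1-1 (AT1G44110) in cluster 8 and CYCB1-2 (AT5G06150) in cluster 9. N57 cells lay in cluster 11 (21.7%), with PEAR2 (AT5G02460), DOF6 (AT3G45610) and TMO6 (AT5G60200) among its 10 leading genes, and in cluster 3 (14.5%), and P3Y cells were spread over clusters 7 (19.2%), 3 (16.9%) and 11 (7.91%). Within PD3 the sieve-element-like share ranged from 40.7% to 80% between its 5 pools. The deltaP3Y share depended on the clustering, with 48.5% at resolution 0.5 and 42.4% with names from 1 in 3 markers.

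**Figure D1:**
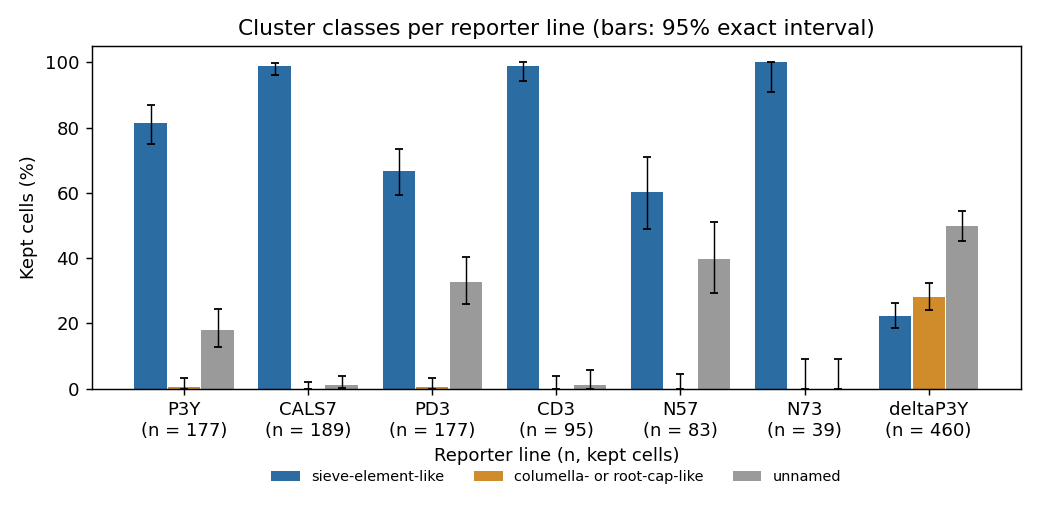
Share of kept cells (percent, vertical axis) in each class for the 7 reporter lines (horizontal axis), with error bars for exact 95% intervals. Sieve-element-like cells made up 100% of N73 and 22.2% of deltaP3Y.

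PD3 and CALS7 shared 5 pools, and the question was how cells of a pair of lines with the same cell type label differed. Late sieve element genes were lower in PD3, with a list median of -3.98 (pools -5.08 to -3.03) and 10 of 12 members at least 2-fold lower in every pool. RTM2 (AT5G04890), a phloem protein that restricts movement of a plant virus, had a level of 166.9 against 4543 (-5.54), and RTM1 (AT1G05760) 45.6 against 1418 (-5.84). The transcription factor NAC045 (AT3G03200), a regulator of enucleation, stood at 152.9 against 1855 (-3.93), and the nuclease NEN4 (AT4G39810) that acts downstream of it at 40.4 against 1011 (-5.51). The CALS7 gene (AT1G06490), a callose synthase of sieve plates, had a ratio of -3.37 and APL (AT1G79430), a transcription factor of phloem identity, -2.38. Genes of dividing cells were higher in PD3: the cell cycle median was 4.25 (pools 3.58 to 4.44, 17 of 21 members at least 2-fold higher in every pool), with CYCB1-1 (AT4G37490) at 130.8 against 4.04 (5.44) and the cytokinesis syntaxin KNOLLE (AT1G08560) at 178.2 against 7.45 (5.08).

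Stem cell niche and PLETHORA genes were higher in PD3 as well (median 3.83, pools 2.39 to 4.50, 4 of 6), with PLT1 (AT3G20840) at 4.55, BBM (AT5G17430) at 4.35, PLT2 (AT1G51190) at 4.15 and PLT3 (AT5G10510) at 3.51. ROP signalling genes had a median of 1.93 (pools 1.08 to 2.80, 6 of 11 higher), among them the exchange factors ROPGEF3 (AT4G00460) (5.41) and ROPGEF5 (AT5G05940) (4.31) and the GTPases ROP2 (AT1G20090) (4.04) and ROP6 (AT4G35020) (3.24). Early phloem regulators had a median of 0.85 (pools 0.31 to 1.66), with 4 of 17 higher (MAKR5 (AT5G52870) 3.52, SMXL5 (AT5G57130) 2.84, PEAR2 2.49, OPL2 (AT2G38070) 2.20) and 1 lower, BRX (AT1G31880) at 34.5 against 444.97 (-3.78). Among procambium and xylem genes, SHR (AT4G37650) (5.08), CNA (AT1G52150) (3.86), PHV (AT1G30490) (3.28) and LHW (AT2G27230) (2.37) were higher, with a list median of 0.40 (pools 0 to 0.52). The columella and root cap list had a median of 0.41 that rested on 1 pool (0.0026 to 0.79 with each pool left out), with the auxin carrier PIN3 (AT1G70940) higher (4.26), and the companion cell list 0.80 (pools 0 to 2.44), with the proton pump AHA3 (AT5G57350) lower (-2.92). Wounding and protoplasting stress genes had a median of 2.77 (pools 0.46 to 5.17), with WRKY40 (AT1G80840) (4.87), TCH3 (AT2G41100) (4.24) and TCH4 (AT5G57560) (4.02) higher in every pool.

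The largest ratios in favour of PD3 included those of the subtilase SBT4.12 (AT5G59090) (7.95), the peptide gene CLE5 (AT2G31083) (7.62), the cell wall gene XTH15 (AT4G14130) (7.19) and BZIP9 (AT5G24800) (6.72). The largest in favour of CALS7 were AT3G25855 (-6.52), AT1G68180 (-6.38), ESM1 (AT3G14210) (-6.12), the phospholipase PLDALPHA3 (AT5G25370) (-5.89) and RTM3 (AT3G58350) (-5.75). Among random lists the late median lay at percentile 1.09, the early phloem median at 58.7 and the cell cycle median at 100. Over 6692 genes the median ratio was 1.23, so the early phloem median lay below the shift, and it changed sign to -0.10 with median-ratio size factors. The ROP signalling median, at percentile 94.4 of random lists, fell to 1.01 with median-ratio size factors and 0.95 with pseudocount 10. Among sieve-element-like cells alone, which were 66.7% of PD3 and 98.9% of CALS7 and lay most often in clusters 8 and 9 against 4 and 5, the stress median was 0.26, SBT4.12 1.99 and CLE5 0.97.

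CD3 and CALS7 were compared in 3 pools (95 and 96 cells), again as lines with the same cell type label. In CD3, late sieve element genes were lower, with a median of -7.07 (pools -8.09 to -5.49) and 11 of 12 members at least 2-fold lower in every pool. RTM2 had a level of 6.35 against 4542 (-9.42), NAC045 18.4 against 1859 (-7.41), and SEOA (AT3G01670), which encodes a filament protein of sieve elements, 0.326 against 440.2 (-8.31). ENODL9 (AT3G20570) (-8.17), NEN4 (-8.03), NEN1 (AT5G07710) (-6.73) and NAC086 (AT5G17260) (-5.64) were lower too, whereas APL was 340.6 against 496.5 (-0.55). Early phloem regulators were higher in CD3 (median 1.56, pools 1.26 to 1.92, 9 of 17), including the DOF factors HCA2 (AT5G62940) (4.29) and PEAR2 at 367.9 against 23.4 (3.93), SMXL4 (AT4G29920) (2.80) and the phosphatase CVP2 (AT1G05470) (2.42). BRX was the only member at least 2-fold lower (-2.74).

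Of 21 cell cycle genes, 18 were higher in CD3 (median 4.76, pools 3.62 to 5.40), with CDKB2-1 (AT1G76540) at 6.75, CYCB1-1 at 6.67 and KNOLLE at 329.8 against 7.47 (6.45). ROP signalling genes had a median of 2.52 (pools 1.80 to 2.75, 6 of 11 higher), with ROPGEF3 at 6.11 and ROP2 at 4.42, and niche genes 2.32 (pools 1.95 to 2.38, 4 of 6), with PLT3 at 3.33 and BBM at 3.22. No stress gene was at least 2-fold apart in every pool, and the list had no clear direction, with a median of -0.12 over genes averaged across pools but 0.011 to 0.42 within pools. The procambium and xylem median was 0, with SHR (2.73) and LHW (2.56) among 4 genes higher and PHB (AT2G34710) lower (-1.47). The columella and root cap median was 0.22 (pools 0 to 0.64), with the cellulase gene CEL5 (AT1G22880) higher (2.55), and the companion cell median -0.12, with AHA3 lower (-3.12). The largest ratios in favour of CD3 included 3xHMG-box2 (AT4G23800) (7.34), ENODL15 (AT4G31840) (7.32), CYCB1;4 (AT2G26760) (7.05), the mitotic activator CDC20.1 (AT4G33270) (6.78) and the microtubule protein EB1C (AT5G67270) (6.63), and in favour of CALS7 AT5G20970 (-9.51), the sucrose synthase SUS6 (AT1G73370) (-8.75) and DAR2 (AT2G39830) (-8.70). The median over 5530 genes was 0.72, and the late, early phloem and cell cycle medians lay at percentiles 0.76, 95.8 and 100 of random lists. The early phloem median fell to 0.94 with median-ratio size factors.

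CD3 and PD3 shared the same 3 pools (95 and 87 cells), and by list medians this pair differed most in stress genes. The stress list was lower in CD3 (median -4.05, pools -4.70 to -3.27), with 6 of 8 members at least 2-fold lower in every pool, among them the wound-responsive factor WRKY40 (-5.55), the touch genes TCH3 (-5.49) and TCH4 (-4.70), and ZAT10 (AT1G27730) (-4.39). Early phloem regulators were higher in CD3 (median 1.08, pools 0.50 to 1.41, 4 of 17 in every pool), with CVL1 (AT2G32010) at 1.72, PEAR2 at 1.60, BRX at 1.55 and CVP2 at 1.46. The late sieve element median was -2.23 but ranged from -4.48 to 0.28 between pools, and APL was higher (1.76). SEOR1 (AT3G01680) (-4.05), SEOA (-4.99) and ENODL9 (-4.46) were lower in every pool, though 1 PD3 cell gave 88.005%, 77.2% and 73.8% of their PD3 signal. Cell cycle genes had a median of 0.59 (pools -0.22 to 1.04) with KNOLLE higher in every pool (1.52), ROP signalling 0.40 (pools -0.26 to 0.82) with ROPGEF1 (AT4G38430) higher (1.34), and niche genes -0.89 (pools -1.39 to -0.22) with none at least 2-fold apart in every pool.

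Some markers of other tissues were lower in CD3 in every pool: the sucrose exporter SWEET12 (AT5G23660) (-6.66) and the sucrose carrier SUC2 (AT1G22710) (-4.09) of the companion cell list (median -0.68, pools -1.29 to 0), PIN3 (-3.08) of the columella and root cap list (-0.83), and SHR (-2.11) and CNA (-1.38) of the procambium and xylem list (-0.11). The columella and root cap median rested on 1 pool (-2.23, and 0 in the others) and ran from -1.41 to 0.087 with each pool left out. The largest ratios in favour of PD3 were SBT4.12 at 2.15 against 1544 (-9.00), the lignin pathway genes CCoAOMT1 (AT4G34050) (-8.08) and PAL1 (AT2G37040) (-7.87), CLE5 (-8.00), XTH15 (-7.86) and GSTF9 (AT2G30860) (-7.64). Those in favour of CD3 were smaller, with EDA18 (AT2G34920) at 3.18, RIP3 (AT3G53350) at 2.52, the tubulin TUB8 (AT5G23860) at 2.36 and the peptide gene CLE26 (AT1G69970) at 2.22. SBT4.12 and CLE5 were leading genes of the unnamed cluster 12, and CCoAOMT1 and PAL1 of the unnamed cluster 15. Over all PD3 pools, not only the shared ones, these clusters held 16.4% and 7.91% of PD3 cells. They held no CD3 cell (up to 3.81%). The median over 6524 genes was -0.23, with the late, early phloem and stress medians at percentiles 0.05, 100 and 0 of random lists. Among sieve-element-like cells alone, most often of clusters 7, 8 and 9 in CD3 and 8 and 9 in PD3, the stress median was -0.22, SWEET12 -1.28, PAL1 -1.18 and the niche median -1.72, and SUC2 (0.016) and PIN3 (0.81) changed sign.

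N57 and P3Y, also labelled PSE, were compared within a single pool (83 and 91 cells), so no second pool repeats the values. In N57, late sieve element genes were lower (median -5.67, 11 of 12), with RTM2 at 3.97 against 745 (-7.23), NAC045 at 19.4 against 966 (-5.56), ENODL9 at -7.12 and the CALS7 gene at -2.94. With medians over cells in place of means the late median was -1.39, and 93.5% of gene ratios in the pairs of this pool moved by over 1.5-fold. Under that setting the companion cell, stress, and procambium and xylem medians were each 0. APL was the exception among late genes, at 306.4 against 427.7 (-0.48). On the median, early phloem regulators were alike (0.012), with HCA2 (1.63) and OPS (AT3G09070) (1.35) higher in N57 and BRX lower (-1.94). Genes of the companion cell list were higher in N57 (median 1.77, 6 of 9), with the sucrose exporter SWEET11 (AT3G48740) at 46.9 against 0.274 (5.23) and SUC2 at 46.6 against 10.3 (2.08), 1 cell giving 40.5% and 38.8% of the N57 signal. These genes did not mark the same cluster. SWEET11 was highest in the unnamed cluster 15 (3.66 per 10000, with SUC2 at 0.151), and SUC2 in the unnamed cluster 1 (2.17). Cluster 15 held 21.7% of N57 cells and 2.26% of P3Y cells over both P3Y pools. SAPL (AT3G12730), FTIP1 (AT5G06850) and SWEET12 were listed at 0 in P3Y in this pool.

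Procambium and xylem genes were lower in N57 (median -0.73, 8 of 20), with the xylem peptidases XCP1 (AT4G35350) (-7.15) and XCP2 (AT1G20850) (-7.38), CNA (-2.80) and the receptor kinase PXY (AT5G61480) (-1.88), and 1 P3Y cell gave 39.3% of XCP1 and 30.3% of XCP2. The niche median was -0.47, with PLT1 higher (1.34) and PLT2 (-1.67) and BBM (-1.66) lower. The ROP signalling median was -0.26, with ROPGEF3 lower (-1.49), and the stress median 0.67, with HSP70 (AT3G12580) higher (1.09). The columella and root cap median was -0.027. The cell cycle median was 0.10, with CYCA1-1 lower (-1.54), and it changed sign to -0.28 with each cell scaled to 1000000. The largest ratios in favour of N57 included CYP79B2 (AT4G39950) (6.49), an enzyme of tryptophan-derived glucosinolates, whose paralogue CYP79B3 (AT2G22330) was at 67.8 in N57 and listed at 0 in P3Y, the laccase LAC1 (AT1G18140) (5.24) and UMAMIT20 (AT4G08290) (5.72, 62.5% from 1 cell), and in favour of P3Y PLDALPHA3 (-8.23), AT1G13920 (-8.16) and HVA22F (AT2G42820) (-7.48). The median over 6200 genes was 0.015, with the late, early phloem and companion cell medians at percentiles 0, 60.7 and 100 of random lists. Among sieve-element-like cells alone, most often of clusters 11 and 3 in N57 and 7 and 11 in P3Y, the companion cell median was 0, the procambium and xylem median -0.081, SWEET11 0.036, XCP1 -0.81 and CYP79B2 1.68, and SUC2 changed sign (-0.029).

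Many of these N57 values depended on the P3Y pool, because P3Y cells of its other pool, set against N57 across pools, gave a late median of -3.12, with RTM2 at -2.74 and NAC045 at -3.84. The P3Y pools also differed in depth. The other pool had a median of 1063634 fragments (lowest 2855), with 72 of 86 kept cells at 50000 or more. The shared pool had 281543 (lowest 51733), with 91 of 91. The early phloem median became -1.43, the cell cycle median -1.34, the niche median -1.98, the stress median -0.29 and the companion cell median 0.053. HCA2 (-0.98), OPS (-0.037), PLT1 (-2.16), HSP70 (-0.36), SWEET12 (-2.73), NEN4 (0.58) and XCP1 (0.013) changed sign, and SUC2 (0.053) and XCP2 (0.0036) no longer differed by 2-fold. SWEET11 (4.68), the CALS7 gene (-3.52), ENODL9 (-6.82) and BRX (-1.77) kept their direction, as did CYP79B2 (1.65), but only 3 of the 20 genes with the largest ratios were named again.

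N73 and P3Y were compared in the same single pool (39 and 91 cells), and here late genes were on the other side. Late sieve element genes were higher in N73 (median 1.88, 11 of 12), with the CALS7 gene at 1807 against 390.2 (2.21), NAC045 at 3574 against 966 (1.89), SEOR1 at 2.06 and RTM2 at 1.94. The median was 7.71 when medians over cells replaced means. Early phloem regulators were lower in N73 (median -1.80, 12 of 17), with HCA2 (-4.99), SMXL5 (-4.31), PEAR2 (-3.99) and TMO6 (-1.80), while BRX was higher (1.33) and OPS was listed at 0 in N73. All 21 cell cycle genes were lower (median -2.70), with KNOLLE at -5.41, the replication clamp PCNA2 (AT2G29570) at -4.47 and CYCB1-1 at -4.07. ROP signalling genes had a median of -1.64 (7 of 11 lower), with ROPGEF3 (-4.96) and ROP2 (-3.75) lower and ROP3 (AT2G17800) (1.25) and ROP5 (AT4G35950) (1.34) higher, 1 cell giving 54.3% of the N73 signal of ROP5, which changed sign to -2.73 with medians over cells. Stress genes were lower (median -3.35, 6 of 8), with TCH4 (-5.39) and WRKY40 (-4.54). With medians over cells the cell cycle, ROP signalling, stress, niche, and procambium and xylem medians were each 0, and the early phloem median was -4.26.

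Procambium and xylem genes had a median of -1.24 (12 of 20 lower), with XCP1 (-7.29) and XCP2 (-7.11) lowest and PXY higher (1.46). The niche median was -1.002, with BBM lower (-3.30), the columella and root cap median -0.16, with PIN3 lower (-3.65), and the companion cell median 0, with AHA3 higher (2.19). Other large ratios in favour of P3Y were SKS6 (AT1G41830) (-6.23), the expansin EXPA4 (AT2G39700) (-5.77) and the cellulose synthase IRX3 (AT5G17420) (-5.90, 53.9% of the P3Y signal from 1 cell). Most genes with the largest ratios in favour of N73 drew most of their signal from 1 cell, such as APL4 (AT2G21590) with 98.4% of its signal, whereas SOM (AT1G03790) (5.45) drew 39.8% from 1 cell. The median over 5843 genes was -0.42, with the late, early phloem and cell cycle medians at percentiles 98.2, 0.05 and 0 of random lists. Among sieve-element-like cells alone, most often of clusters 10, 4 and 13 in N73 and 7 and 11 in P3Y, the stress median was -0.29, the ROP signalling median -0.86 and the procambium and xylem median -0.078, and WRKY40 changed sign (0.011). Against P3Y cells of its other pool the late median was 3.31, the early phloem median -3.50, the cell cycle median -4.47 and the stress median -3.77. The procambium and xylem median was -0.061 there, the ROP signalling median -2.65 and the niche median -2.72. SEOR1 (-0.69), ROP5 (-0.46) and XCP2 (0.27) changed sign there, XCP1 was at -0.12, and 4 of the 20 genes with the largest ratios were named again.

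N57 and N73 from the same pool were compared last (83 and 39 cells). All 12 late sieve element genes were lower in N57 (median -7.57, or -8.58 with medians over cells), with ENODL9 (-9.17), RTM2 (-9.17), NAC045 (-7.45), the CALS7 gene (-5.15) and APL (-1.23). All 21 cell cycle genes were higher in N57 (median 2.72), with KNOLLE at 5.92 and PCNA2 at 4.62. Also higher were early phloem regulators (median 1.90, 14 of 17), with HCA2 (6.62), SMXL5 (4.95) and PEAR2 (4.01), and BRX lower (-3.27). Stress genes had a median of 3.58 (6 of 8 higher), with TCH4 (6.12) and WRKY40 (5.16). The companion cell median was 1.77 (6 higher, AHA3 lower at -2.07), the ROP signalling median 0.51, with ROP2 higher (4.20) and ROP3 lower (-1.49), and the niche median 0.52. With medians over cells the cell cycle, stress and companion cell medians were each 0, and the early phloem median was 4.03. The procambium and xylem median and the columella and root cap median were both 0.

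The largest ratios in favour of N57 included MS2 (AT3G03780) (7.99), the lignin pathway genes 4CL1 (AT1G51680) (7.66) and 4CL2 (AT3G21240) (7.17), GASA1 (AT1G75750) (7.56) and the amino acid transporter SIAR1 (AT1G44800) (7.33), and those in favour of N73 were AT1G13920 (-10.14), PLDALPHA3 (-9.53) and RTM3 (-9.25). MS2, 4CL1, GASA1 and SIAR1 were leading genes of the unnamed cluster 15, which held 21.7% of N57 cells and none of N73 (up to 9.03%). The median over 6425 genes was 0.79, with the late, early phloem and cell cycle medians at percentiles 0.13, 99.8 and 99.9 of random lists. Among sieve-element-like cells alone, most often of clusters 11 and 3 in N57 and 10, 4 and 13 in N73, the stress median was 0.72, the companion cell median 0.015 and 4CL2 -0.15.

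**Figure D2:**
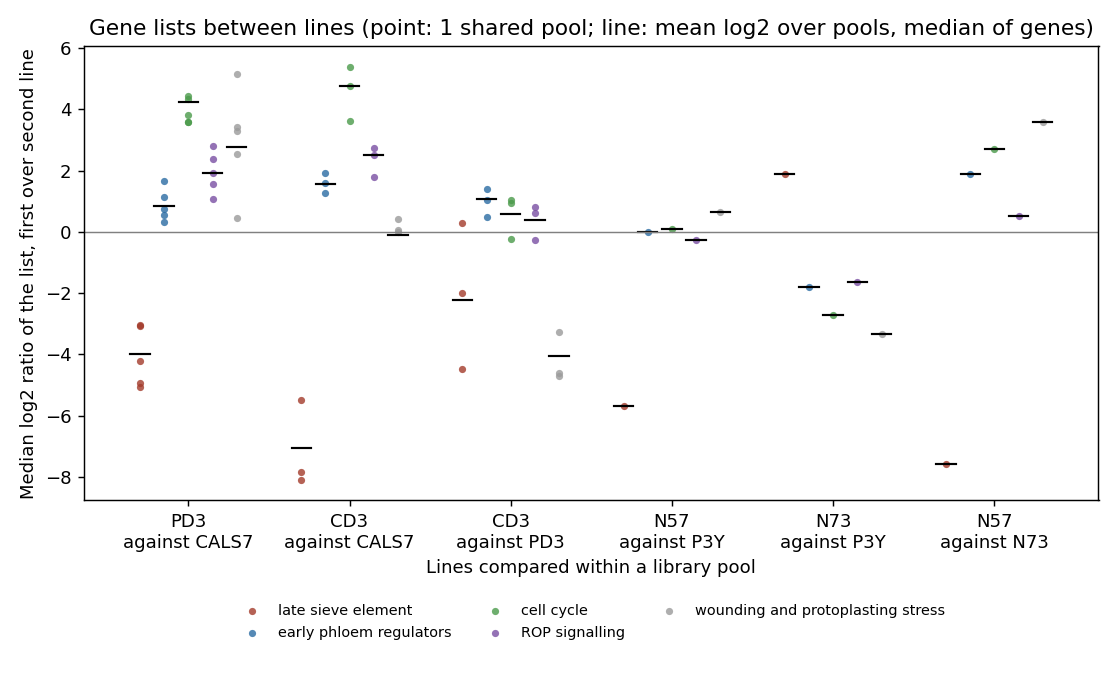
Median log2 ratio of 5 gene lists (vertical axis) for the pairs of lines that shared pools (horizontal axis), with a point for each pool and a short line for the value over pools. Over pools, late sieve element medians ranged from -7.57 in N57 against N73 to 1.88 in N73 against P3Y.

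The comparison of deltaP3Y with P3Y asked what the line labelled with several cell types held beside the line of similar name, but no pool held both, so the effect of the line and that of the pool cannot be told apart. Columella and root cap genes were higher in deltaP3Y (median 3.35), with 7 of 8 above P3Y in every pool, among them the root cap factors SMB (AT1G79580) at 25.2 against 0.516 (4.11) and FEZ (AT1G26870) (4.23), NCED2 (AT4G18350) at 51.1 against 1.51 (4.38) and CEL5 at 153.1 against 10.2 (3.79). BRN1 (AT1G33280) and BRN2 (AT4G10350), related root cap factors, were listed at 0 in P3Y. Early phloem regulators were lower (median -2.80, 14 of 17), with PEAR2 at 33.3 against 411.04 (-3.59), CVL1 (-3.36) and TMO6 (-3.20), as were late sieve element genes (median -1.78, 8 of 12), with SEOR1 (-3.78), the CALS7 gene (-2.79) and APL (-2.54). The late sieve element median was -0.98, under 2-fold, against P3Y cells of the pool without other lines alone. Of 21 cell cycle genes 20 were lower (median -2.77) and RNR2A (AT3G23580) was higher (1.75), and of 11 ROP signalling genes 9 were lower (median -1.78), with ROPGEF3 at -4.82.

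Procambium and xylem genes were mixed in deltaP3Y (median -0.52), with the auxin response factor MP (AT1G19850) at 103.4 against 10.99 (3.12), ATHB8 (AT4G32880) at 65.7 against 12.7 (2.28) and ACL5 (AT5G19530) (2.20) higher and 5 of 20 lower. PLT1 was higher at 60.9 against 6.70 (3.01), while the niche median was -0.031. The stress median was 0.30, with WRKY33 (AT2G38470) (2.50), ZAT10 (1.68) and HSP70 (1.03) higher. The companion cell median was -0.034. Against P3Y cells of the pool shared with N57 and N73 alone, the early phloem median was -1.87, the cell cycle median -1.95 and the stress median 1.39.

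The last comparison followed sieve-element-like cells of all lines along an order, to see which gene groups changed along it. These cells came from clusters named by the early phloem or the late sieve element list. Contrasts between these lists along an order were therefore partly set by that choice of cells. The planned order by diffusion pseudotime began at a deltaP3Y cell of cluster 11, in the middle of the series of clusters, and placed both dividing and late cells toward its end. Its last bin held 85 cells of cluster 4, 44 of cluster 13 and 17 of cluster 9. Along it late sieve element genes were 2.00 higher in the last bin than in the first, in natural log units (11 of 12 genes higher), in 3 of 4 lines and 8 of 8 pools, but without a steady rise, at 0.867, 1.26, 0.389, 0.377 and 2.86 in bins 1 to 5. Early phloem regulators differed by -1.07 (16 of 17 lower), but this list set the start of the order, so a fall away from the first bin was built in. Cell cycle genes differed by 0.056, with this sign in 2 of 4 lines and 5 of 8 pools, ROP signalling by -0.22, niche genes by -0.021, procambium and xylem genes by -0.14 and stress genes by -0.12. With each pool left out the cell cycle difference ran from -0.44 to 0.055 and the niche difference from -0.22 to -0.018, so the sign of the former depended on the pools. The genes with the lowest rank correlation with this order included EXPB1 (AT2G20750) (-0.561), FLA1 (AT5G55730) (-0.503), GH9B1 (AT1G70710) (-0.503) and TUB6 (AT5G12250) (-0.497), and those with the highest ATN (AT3G05330) (0.414), RALFL22 (AT3G05490) (0.407) and IMPL1 (AT1G31190) (0.382).

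The order by the first principal component ran from dividing to late cells, and its rank correlation with the pseudotime order was 0.0763. Cluster 9 had a median position of 8.05%, cluster 8 16.9%, cluster 11 49.8%, cluster 5 67.2% and cluster 4 92.4%. Late sieve element genes went from 0.113 in the first bin to 3.10 in the last, with all 12 higher. This direction of the list held in 3 of 3 lines and 8 of 8 pools with enough cells at both ends. The rise was partly built in, because bin 5 held only clusters 4 (75 cells), 13 (43) and 10 (28), which were named by late markers. Bins 1 and 2 held only clusters named by early phloem markers. In pools holding CALS7, the pool direction largely restated the line difference, because CALS7 had 0 cells in bin 1 and 84 in bin 5. PD3 had 72 and 5 cells in these bins, and CD3 had 26 and 0. Those pools are therefore not separate repeats of a change within a line. NAC086 reached 1.02 by bin 3 and 3.66 by bin 5, NAC045 0.457 and 4.08, ENODL9 0.306 and 4.40, and RTM2 0.205 and 4.18, while APL (2.65) and the CALS7 gene (2.90) were highest in bin 4. Early phloem regulators were highest in bin 3 (1.40) and lowest in bin 5 (0.248), with TMO6 going from 3.06 to 0.22 and PEAR2 from 2.10 to 0.0202. BRX was the exception among them, at 0.32 in bin 1, 2.37 in bin 4 and 2.04 in bin 5.

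Cell cycle genes were at 0.895 in the first bin of this order and 0.0266 in the last (20 of 21 lower). Mitotic KNOLLE was highest in bin 1 (1.65), and the replication genes MCM2 (AT1G44900) (0.629) and PCNA1 (AT1G07370) (0.776) in bin 2. Bin 1 was mostly clusters 9 (59 cells) and 8 (46), and bin 2 mostly clusters 3 (53) and 7 (40). KNOLLE was a leading gene of cluster 9, and MCM2 and PCNA1 of cluster 3. Cell cycle phase and maturation were not told apart in these bins. ROP signalling genes went from 0.662 to 0.0949, with ROPGEF3 highest in bin 1 (1.02) and ROPGEF1 in bin 3 (1.40). Niche genes went from 0.49 to 0.0186, with PLT3 at 1.02 and 0.057. Procambium and xylem genes differed by -0.28, with 7 of 9 lower and PHB and PXY higher, stress genes by 0.012, and columella and root cap genes by -0.16. Of the companion cell list only AHA3 was detected in enough cells, with its highest value in bin 4 (1.46).

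Among genes outside the lists, those with the highest rank correlation with the order by the first principal component were UBQ11 (AT4G05050) (0.699), the small GTPase RABC2A (AT5G03530) (0.679), the cysteine protease RD19 (AT4G39090) (0.645) and APS2 (AT1G05610) (0.594). UBQ11 shares near-identical polyubiquitin copies, so its identity is uncertain. The lowest included the ribosomal protein genes P40 (AT1G72370) (-0.671), EMB1080 (AT3G48930) (-0.656) and RP1 (AT1G43170) (-0.648), and UBQ5 (AT3G62250) (-0.652). Of ordered PD3 cells 61.02% were in bin 1, and of N57 cells 56% in bin 3, while CALS7 cells were in bins 4 (52.9%) and 5 (44.9%) and N73 cells in bin 5 (64.1%). CD3 had no cell in bins 4 and 5 (up to 3.85% in each). By pseudotime the lines were placed differently, with CALS7 cells in bins 1 (25.7%), 2 (24.1%) and 5 (42.8%) and CD3 cells in bins 4 (32.98%) and 5 (11.7%) as well. The median number of genes detected at 50000 fragments per cell was 6915, 6200, 5206, 4076 and 2272 in bins 1 to 5 of the order by the first principal component, and the 50 most abundant genes of a cell took 14.3% of fragments in bin 1 and 35.5% in bin 5. Along the pseudotime order the number of genes did not fall steadily, at 4944, 4386, 6438.5, 6643.5 and 2155 in bins 1 to 5.

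**Figure D3:**
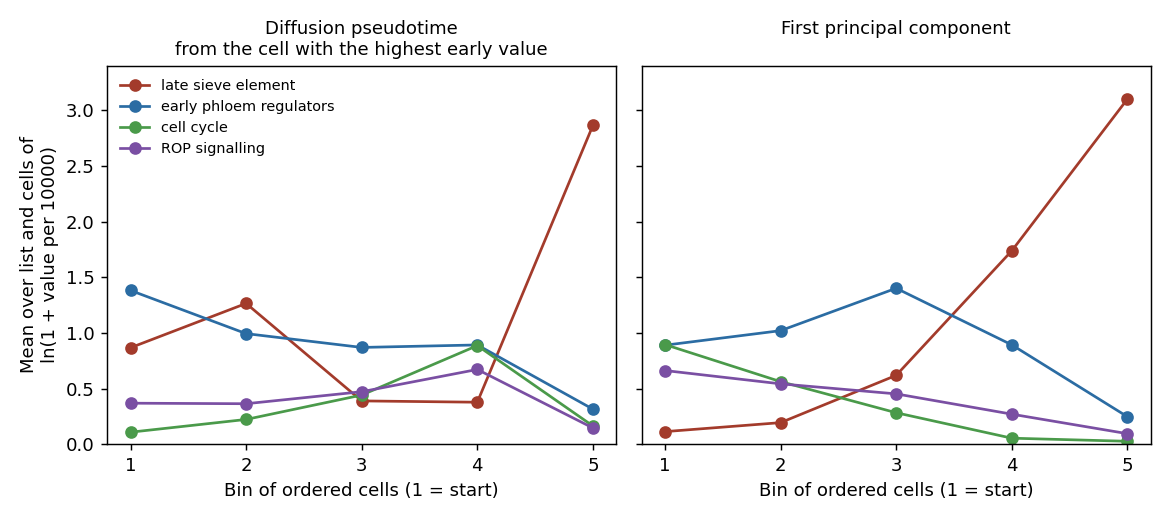
Mean natural log level of 4 gene lists (vertical axis) in the 5 bins of each order (horizontal axis). Late sieve element genes ended at 3.10 by the first principal component and 2.86 by pseudotime.

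**Figure D4:**
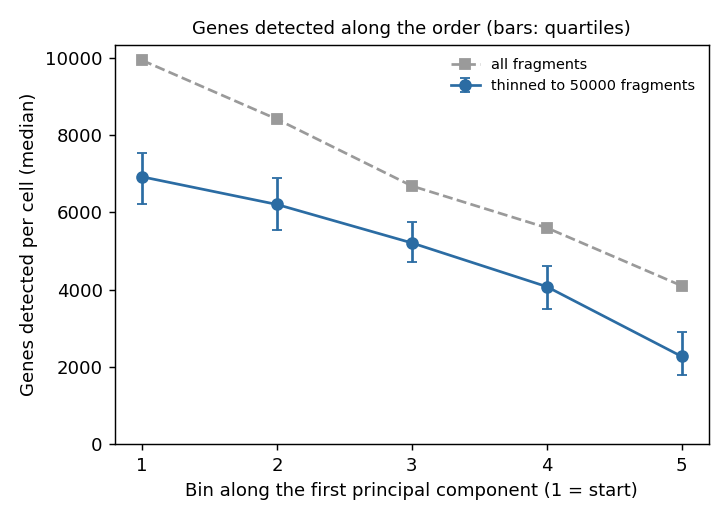
Median genes detected per cell (vertical axis) in the 5 bins of the order by the first principal component (horizontal axis), from all fragments and at 50000 fragments, with error bars for quartiles. At 50000 fragments the median was 6915 in the first bin and 2272 in the last.

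For scale, the same line was compared between pools by the median size of the log2 ratio over genes. P3Y differed by 1.07 between its pools, where late sieve element genes had a median of -1.50 and early phloem regulators 1.61 for the pool without other lines against the pool shared with N57 and N73. The range was 0.41 to 0.73 in CALS7, 0.29 to 0.77 in PD3, 0.25 to 0.48 in CD3 and 0.19 to 0.29 in deltaP3Y. Between lines in the same pool it was 1.63 to 2.30 for PD3 and CALS7, 1.63 to 1.97 for CD3 and CALS7, 0.63 to 0.94 for CD3 and PD3, 0.41 for N57 and P3Y, 1.28 for N73 and P3Y and 1.78 for N57 and N73.

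The empty wells, 1 in each of 5 pools, held 6806, 6680, 5010, 3519 and 5404 fragments of 3538, 3585, 2789, 2074 and 2764 genes. This was 0.192% to 0.456% of the median of cells in the same pool, and every well would have passed the cell filter. Transcripts of sieve element genes were among them, with 42, 16, 8, 43 and 54 fragments of late sieve element genes in wells 1 to 5. Of kept cells, 22 had no more fragments than the fullest well.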

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

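Both tests weighed in this part were written down before their results were seen, and none was chosen afterwards. The test of a constant background was, however, run on more pools than written down. The random draws given beside the test of a shared index were not part of that test as written down. Procambium and xylem genes in empty well 5 stood far from the other wells, at 1295 per 1000000 against 449.1 in the next well, from 7 fragments of 4 genes. Pericycle genes in empty well 3 also stood apart, at 399.2 per 1000000 from 2 fragments of 1 gene. These came from 13 sets of 5 wells examined for a value far from the rest, and chance alone marks about 1 in 20 such sets of continuous values. The values rested on few fragments, and the pericycle set was at or near 0 in the other wells, so 2 fragments of these genes were enough to set a well apart and the rate does not apply to it. Signal was also present in data that no comparison used: 99 libraries removed by the cell filter held more fragments than the fullest empty well, 98 of them for an organelle share over the limit, with a median of 55.1%, and 61 were from deltaP3Y.

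Transcripts in the empty wells were weighed against a pair of technical explanations, and no biological explanation was tested. Fragments carried over through a shared index: the profile of 5 of 5 wells was closer to the cells that share an index with the well than to the other cells of the pool, with correlations of 0.735 against 0.679 in well 1 and 0.732 against 0.652 in well 5. As many cells of the same lines were also drawn at random from the whole pool, cells that share an index included. In each well, 0 of 1000 such draws came as close. A constant background from all libraries of the pool: 2 of 5 wells were closer to the cells of their own pool than to other pools, which left this open. Part of the signal in the wells may therefore have come from cells that share an index in the same pool.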

How the results depend on the processing

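A minimum of 50000 fragments per cell, medians over cells, P3Y cells of its other pool, names from 1 in 3 markers, a start at the first cell by the first principal component and thinning were chosen after seeing the data. Filters of 2000 genes, 500 genes or no organelle limit moved 0, 4 and 1 gene ratios, and no gene ratio of at least 2-fold changed sign under any filter, scaling, pseudocount or left-out pool. Pseudocount 10 moved 75.3% of gene ratios, scaling each cell to 1000000 41.2%, median-ratio factors 36.998%, only sieve-element-like cells 36.6% and 50000 fragments 15.2%. Medians over cells moved most, 93.5% of gene ratios in the 3 pairs within a single pool, and the other P3Y pool moved 67.3%. No paired analysis was possible because equal cell numbers in different lines name unrelated cells, and lines were matched only by shared pool. The sieve-element-like share of the 6 lines labelled PSE (83.2%) became 88.3% at resolution 0.5, 88.2% centred per pool and 88.03% with names from 1 in 3 markers. The late sieve element median became -4.93 (median-ratio factors) and -4.81 (50000 fragments) for PD3 against CALS7, -5.63 (pseudocount 10) and -7.87 (50000 fragments) for CD3 against CALS7, -1.35 and -1.63 likewise for CD3 against PD3, -4.87 (each cell to 1000000), -4.34 (pseudocount 10), -1.39 (medians over cells) and -3.12 (other P3Y pool) for N57 against P3Y, 2.51 (median-ratio factors), 7.71 (medians over cells) and 3.31 (other P3Y pool) for N73 against P3Y, and -8.35 (median-ratio factors), -5.99 (pseudocount 10) and -8.58 (medians over cells) for N57 against N73. With each pool left out it ran from -4.29 to -3.78 for PD3 against CALS7, -7.91 to -6.60 for CD3 against CALS7 and -3.77 to -0.57 for CD3 against PD3, and the late gene difference along the order from 1.92 to 2.80. With only sieve-element-like cells these changed sign: in CD3 against PD3 the reference gene median (0.050), SUC2 (0.016), PIN3 (0.81), HSP70 (0.83), ACT2 (AT3G18780) (0.19), UBQ10 (AT4G05320) (0.050) and ZAT12 (AT5G59820) (0.43); in N57 against P3Y SUC2 (-0.029) and AT1G60680 (-0.016); in N73 against P3Y T5L1 (AT1G68810) (0.14), VND7 (AT1G71930) (0.021), WRKY40 (0.011), ACT2 (0.017), AT3G47400 (0.11) and ZAT12 (1.80); and in N57 against N73 CLE5 (-0.33), 4CL2 (-0.15) and ZAT12 (-0.36). With medians over cells ROP5 changed sign in N73 against P3Y (-2.73) and N57 against N73 (1.90). With the other P3Y pool these changed sign: in N57 against P3Y AT1G68230 (0.50), OPS (-0.037), CASP2 (AT3G11550) (-1.25), HSP70 (-0.36), PLT1 (-2.16), AT3G62040 (-0.20), XCP1 (0.013), NEN4 (0.58), SWEET12 (-2.73) and HCA2 (-0.98); and in N73 against P3Y XCP2 (0.27), T5L1 (0.18), VND7 (0.021), AT1G79620 (0.065), SEOR1 (-0.69), AT3G47400 (0.11), SCR (AT3G54220) (0.016), NCED2 (0.0067), ROP5 (-0.46) and WER (AT5G14750) (-0.18). By the first principal component the late gene difference was 2.99 and the cell cycle difference -0.87, and from the first cell by that component 2.98 and -0.72. Depth limits the shallow cells most, and 34 ordered cells could not be thinned. The cause was not tested for any of these changes.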

Other observations

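In this part the test of library depth, the test within pools and the test within sieve-element-like cells were chosen after their results were seen, and the other tests before. Reference genes did not move together between lines: UBQ10 was lower in PD3 than in CALS7 (611 against 4109, -2.74) and lower in CD3 than in CALS7 (-4.47), whereas the elongation factor EF1A (AT5G60390) (2.55 and 2.67) and the actin ACT7 (AT5G09810) (1.75 and 1.28) were higher. UBQ10 was higher in N73 than in P3Y (1.74) and lower in N57 than in P3Y (-1.20) or N73 (-2.94), and its polyubiquitin copies are nearly identical, so its identity is uncertain. The reference list medians were 1.75 for PD3 against CALS7, 0.88 for CD3 against CALS7, -1.04 for CD3 against PD3, 0.29 for N57 against P3Y, -1.20 for N73 against P3Y and 1.54 for N57 against N73. Along the order by the first principal component, UBQ10 went from 1.01 to 4.30, EF1A from 4.79 to 1.21 and ACT7 from 2.92 to 0.64. The phosphate exporter PHO1 (AT3G23430) of the pericycle list was higher in PD3 than in CALS7 (4.58) and in N57 than in P3Y (2.78, but 0.33 against the other P3Y pool), and lower in CD3 than in PD3 (-5.32) and in N73 than in P3Y (-3.49). Among clusters, PHO1 was highest in the unnamed cluster 15, at 9.32 per 10000. List medians over the 6 pairs ran from -1.10 to 0.63 for pericycle, -0.71 to 0.43 for endodermis and -0.27 to 0.21 for cortex, and were 0 for epidermis. For deltaP3Y against P3Y they were -1.08 for pericycle, -0.35 for endodermis, 0.0032 for cortex, 1.06 for epidermis and -0.36 for reference genes. The sign of this endodermis median depended on the P3Y pool. It was 1.25 against P3Y cells of the pool shared with N57 and N73 alone, and -1.03 against those of the other pool alone.

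Cells outside the named classes fell into 6 clusters with distinct leading genes. Cluster 12, with CLE5, CLE6 (AT2G31085) and SBT4.12 among its leading genes, held 16.4% of PD3, 9.64% of N57, 5.65% of P3Y and 1.30% of deltaP3Y cells. Cluster 15, with GSTF9, MS2 and the phenylpropanoid synthesis genes CCoAOMT1, PAL1 and 4CL1 among its leading genes, held 21.7% of N57, 7.91% of PD3 and 2.26% of P3Y cells. Cluster 6, led by ADF9 (AT4G34970), the auxin synthesis gene YUC3 (AT1G04610) and the peptide genes RGF2 (AT1G13620) and RGF3 (AT2G04025), held 18.7% of deltaP3Y cells and tied between root cap and niche markers. Cluster 16, led by WAT1 (AT1G75500) and MIPS1 (AT4G39800), had 8 of 20 procambium and xylem markers and held 6.09% of deltaP3Y and 1.13% of P3Y cells. Cluster 1, led by the auxin carrier LAX3 (AT1G77690) and with 8 of 17 early phloem regulators, held 20.2% of deltaP3Y, 9.04% of P3Y, 8.43% of N57 and 7.91% of PD3 cells. Cluster 19, led by PYK10 (AT3G09260), held 3.48% of deltaP3Y, 1.06% of CALS7, 1.05% of CD3 and 0.565% of PD3 cells.

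Fewer genes were detected per cell at the late end of the order by the first principal component, and 4 technical explanations were weighed. Depth of the libraries did not account for it, since the ratio of the last to the first bin was 0.329 at equal depth. Nor did a few genes taking most of the fragments, since without the 50 most abundant genes of each cell it was 0.374 (2044 against 5467 genes). A difference between reporter lines did not either, as within P3Y alone the ratio was 0.355, from 27 and 12 cells. Because P3Y spans a pair of pools, pools were examined as well: in the 3 sets of cells of 1 line in 1 pool with at least 5 cells in both end bins, the highest ratio was 0.465, in deltaP3Y, and P3Y in the pool shared with N57 and N73 gave 0.332 from 12 and 9 cells. Late cells may therefore express fewer genes, as the ratio of 0.329 allows, but total RNA per cell was not measured and no biological explanation was tested.

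Stress genes were lower in CD3 than in PD3, and a pair of technical explanations was weighed. Shallow libraries did not account for it, since the median was -4.18 with at least 50000 fragments per cell. Within sieve-element-like cells the median was -0.22, so the difference may rest largely on PD3 cells outside those clusters, 32.8% of PD3 against 1.05% of CD3. Whether the PD3 cells outside those clusters responded to protoplasting or held these transcripts in the root was not tested.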
